A study of Mus musculus with 24 samples.

How the data were processed

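Chromatin immunoprecipitation with sequencing (ChIP-seq) was deposited for 4 mouse small cell lung cancer lines, each kept in culture at early passage from a tumour of the RPP model, in which Rb1, Trp53 and Rbl2 are the engineered tumour suppressors. Lines 159-1 and 1014 came from tumours with a control guide RNA (control lines) and lines 236L and 236R from tumours with a guide RNA against Kdm6a (mutant lines). The histone marks H3K4me1, H3K4me2 and H3K27me3 were profiled in all 4 lines and the KDM6A protein in the 2 control lines. Cells were collected 24 h after plating, and the KDM6A libraries had an extra crosslinking step with 2 mM disuccinimidyl glutarate, per the labels' protocols. The labels give H3K4me1 its own set of input libraries, so this mark is treated as a batch of its own, which holds both genotypes.

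The series holds 24 samples, of which 14 have a peak list and the 10 input libraries have none in the files used here. Reads were aligned with Bowtie2 2.4.2 and peaks called with MACS3 3.0.0a7 on mm10, per the submitters' processing notes; the peak calling threshold, the control track and the handling of duplicate reads are not given in the sources used here. Each list belongs to 1 library, so replicates were never pooled. A list holds, for each broad peak, its position, the fold enrichment over background (a linear ratio, deposited by the authors) and the −log10 p-value and −log10 q-value that the authors deposited with it. Folds ran from 1.20 to 35.2 and the lowest −log10 q was 1.01. These values are the authors' own for each peak and served only to rank or filter peaks within a list; peak heights were not compared between lists. No read counts were used, so the sequencing depth of the libraries is unknown here, and a shorter list can come from a shallower or less enriched library as well as from fewer marked sites. That limit applies to every length and count below.

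Peaks on chromosomes 1 to 19, X and Y were used, and the 337 peaks on unplaced contigs over all lists (at most 0.154% of a list) were set aside. Peaks of a library were merged, and 3 measures were taken from them. The first was the total length covered. The second was the state of 1 kb bins of the genome, marked where peaks cover at least 50% of the bin; a bin is called control-only where both control lines and neither mutant line mark it, and mutant-only in the reverse case. The third was the length covered in the window of each of 21887 protein-coding genes, which is the gene body with 10 kb on each side, from an NCBI gene table of the same assembly (GRCm38.p6). A gene was counted as having more or less of a mark in the mutant lines where the lowest line of one group exceeded the highest line of the other by at least 2 kb. A random assignment of the lines to groups separates a gene by any amount in a given direction with a probability of at most 16.7%. Genes of a library can move together, for instance with list length, so the share of genes in these 4 libraries can lie above this without an effect. The gene table has no strand, so windows of 2.5 kb around both gene ends took the place of the promoter windows that had been planned.

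Groups were compared as 2 lines against 2. Such a comparison has 3 splits of the lines, so the smallest p an exact two-sided permutation test can give is 0.333, and by that test no single gene, bin count or length can pass 0.05. Counts are therefore set beside the same counts for the 2 other splits of the lines. Nothing in the labels says that 236L and 236R came from separate animals, so a p-value measures only the spread between these samples.

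14 gene lists with 274 genes (all found in the gene table) and 3 marks gave 42 list tests. Each compared the mean change in the covered share of the gene window over a list's members with 100000 random lists matched on control cover (10 classes) and window length (5 classes), two-sided, with Benjamini-Hochberg adjustment over the 42 tests. Such a p asks whether a list moved differently from other genes within these 4 libraries. Genes are not replicates, and it does not measure the spread between lines. The matching used the control cover of the tested mark alone, so lists can differ from their random lists in control cover of another mark. Lists were also set beside 10000 random lists of the same window lengths within single libraries, as percentiles.

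KDM6A-bound bins are those marked in both control lines. Overlaps with other marks were set beside 1000 circular shifts of the bins along each chromosome. The shifts do not keep nearness to genes, so bins that share such a location can overlap more than shifted bins. Odds ratios of losing or gaining a mark at KDM6A-bound bins were Mantel-Haenszel estimates, stratified for losses by the rank of the control peaks and by nearness to a gene end (20 strata) and for gains by nearness alone, with 95% block jackknife intervals over 10 Mb blocks. These intervals cover variation along the genome, not between lines. Losses were counted among bins marked in both control lines. Gains of H3K27me3 were counted among bins with H3K4me1 or H3K4me2 in both control lines and H3K27me3 in neither.

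The named genes are, per mark, the 10 genes with the largest separation in each direction, 1 per locus; for KDM6A the 10 with the longest cover in both lines; members of the fixed lists with a separation of at least 2 kb; and Neurod1, Insm1, Chga, Foxa2, Nkx2-1, Pou2f3, Yap1, Rest, Hes1, Kdm6a, Kdm6b, Ezh2, Rb1, Trp53 and Rbl2 whatever their values. Not all of these are printed, and 1 gene list and a pair of genes, tested with the others, are not reported here. The measures, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were a stricter threshold (q of 0.001 or lower), lists trimmed by their own p rank to the covered length of the shortest list of the mark, other overlap rules, merged regions in place of bins, windows of 50 kb, gene ends only, a separation of 5 kb, autosomes only, other definitions of the odds ratios, and leaving out each line in turn. For lists, leaving out lines and merging neighbouring members into 1 locus were added after the data were seen, as were all alternatives for single genes, and so were lists of 24 macrophage and 24 lymphocyte genes, written before the values of their members were seen.

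The scripts were tested on simulated data first. In 21887 gene windows built from the H3K4me1 list of line 159-1, all 100 genes made to lose and all 100 made to gain cover were recovered, 257 of 20693 unchanged genes were called, and an odds ratio simulated at 3 was estimated at 2.94. Among 100 random lists, 1 had a permutation p under 0.05. All simulated lines were slightly altered copies of that 1 list, and changed genes lost every peak or gained peaks well beyond the 2 kb threshold. Between real H3K4me1 lists the shared bases made up 0.144 to 0.566 of the joint cover (Jaccard index, 1 for identical lists). These results thus test the scripts and give no error rates for the real lines. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.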

Results

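ChIP-seq peak lists were examined for H3K4me1, a mark of enhancers, H3K4me2, a mark of promoters and enhancers, and H3K27me3, the repressive mark placed by the Polycomb complex PRC2, in 2 control and 2 Kdm6a-mutant mouse small cell lung cancer lines. KDM6A, which removes methyl groups from H3K27 and is a subunit of complexes that methylate H3K4, was mapped in the 2 control lines. The series title ties KDM6A to plasticity between subtypes of this cancer, so the question is which genes differ in these marks between lines with and without the Kdm6a mutation. Peaks numbered 82915 and 88582 for H3K4me1 in 159-1 and 1014 and 71675 and 72199 in 236L and 236R. The same order of lines gave 58368, 56481, 47141 and 45544 peaks for H3K4me2 and 31655, 52080, 10039 and 25230 for H3K27me3. KDM6A had 38785 peaks in 159-1 and 29312 in 1014. Values for the 2 control lines of H3K4me2 are given by sample label, but the deposited names of those 2 lists name the other line, so for this mark 159-1 and 1014 mean the libraries labelled so. The comparison of genotypes is the same under either assignment.

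The Kdm6a locus itself (chromosome X, 18160862 to 18279936, mm10) carried H3K4me2 in all 4 lines, with 3.10 and 4.38 kb covered in 159-1 and 1014 and 6.01 and 4.66 kb in 236L and 236R. A guide RNA mutation need not remove these marks, and KDM6A was not mapped in the mutant lines, so the lists hold no check of the mutation. The depth of the libraries is unknown, since the files hold peaks and no read counts. Among the genes engineered in the RPP model, H3K4me2 covered 8.26 and 12.8 kb at Rb1 in the control lines and 5.13 and 5.33 kb in 236L and 236R. The 4 genes of chromosome Y with at least 1 kb of H3K4me2 in a line (Uty, Ddx3y, Eif2s3y and Kdm5d, named after their values were seen) carried it in both control lines and in neither mutant line. Total cover of chromosome Y did not follow genotype: H3K4me2 covered 24.3 and 18.3 kb of it in 159-1 and 1014 and 22.3 and 12.8 kb in 236L and 236R, and H3K4me1 0, 11.2, 43.7 and 14.2 kb. Chromosome X held a larger share of the cover in both mutant lines for all 3 histone marks. This share was 0.474 and 0.515% of H3K4me1 in 159-1 and 1014 against 1.41 and 1.18% in 236L and 236R. For H3K4me2 it was 1.839 and 1.947% against 2.468 and 2.402%, and for H3K27me3 0.132 and 0.230% against 1.28 and 3.85%. Total cover did not follow the 4 genes either. H3K4me1 covered 0 kb of chromosome Y in 159-1, which had H3K4me2 at all 4, and 43.7 kb in 236L, which had it at none. It is thus no measure of whether these genes are present. The 4 genes and the chromosome X shares go with a difference in sex chromosomes between the groups. Such a difference cannot be told apart from genotype with these 4 lines, so it stays open in every comparison here.

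**Figure D1:**
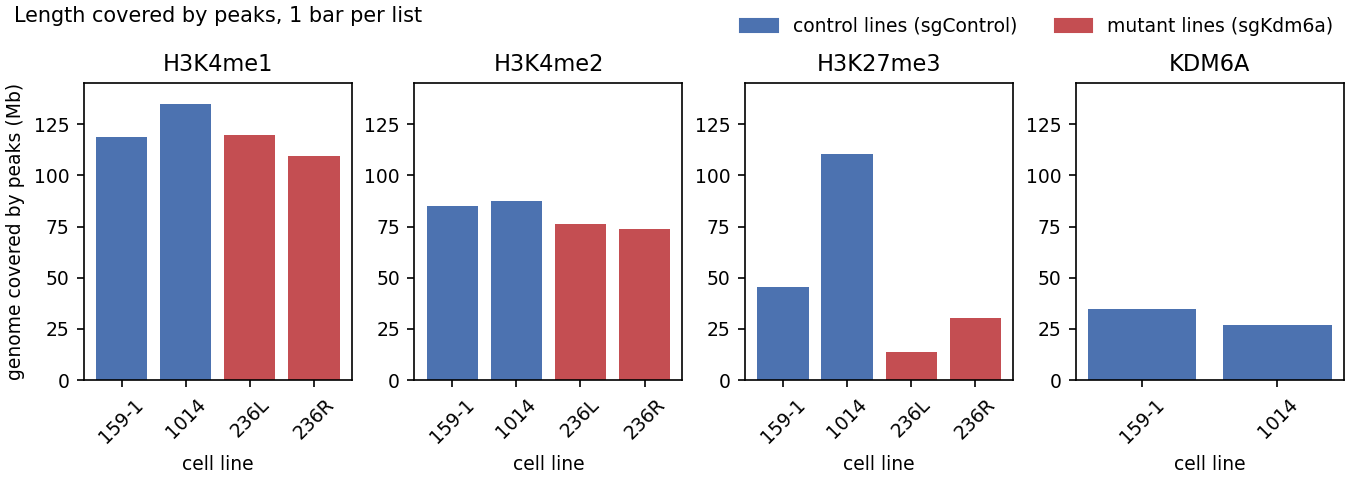
Genome length covered by peaks (Mb) for each of the 14 lists, with control lines in blue and mutant lines in red. H3K27me3 peaks cover 45.4 and 110 Mb in the control lines and 13.8 and 30.5 Mb in the mutant lines, while H3K4me1 covers 119 Mb in 159-1 and 120 Mb in 236L.

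H3K4me1 was at least 2 kb above control in both mutant lines at 25 of 39 HOX genes and 11 of 40 developmental transcription factors. It was below control by long summed lengths at genes such as Camta1, Fto and Msi2. Lengths add all peaks in a gene window, so a ranking by kb favours long genes. At Hoxa3, a patterning transcription factor, peaks covered 0 kb in both control lines, 19.5 kb in 236L and 23.7 kb in 236R. Gata3, a transcription factor of T cells and several epithelia, had 1.19 and 0 kb in the control lines and 15.7 and 12.9 kb in the mutant lines. Camta1, a transcription activator of neurons, had 313 and 363 kb in the control lines against 28.3 and 120.4 kb, and Msi2, an RNA-binding protein of progenitor cells, had 242 and 288 kb against 3.61 and 166 kb. Other genes with the largest separations were the planar polarity gene Prickle2 (13.7, 30.6, 55.1 and 53.6 kb in 159-1, 1014, 236L and 236R) and the collagen gene Col27a1 (6.15, 3.99, 21.3 and 23.1 kb) on the higher side, and Fto (103, 129, 19.9 and 22.7 kb), the cadherin Cdh13 (156, 186, 0 and 77.4 kb) and the calcium channel Cacna1c (145, 208, 10.4 and 67.0 kb) on the lower side.

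For H3K4me1, 1160 of 21887 genes had at least 2 kb more in both mutant lines than in either control line and 1630 had at least 2 kb less. Which count was larger depended on the setting. By any amount, 5489 genes had more and 3225 had less, and the other splits gave 1881 and 1656, and 3167 and 1447. The 16.7% for a random assignment of lines is no bound on these shares, since genes of a library can move together. The counts of more and less were 1611 and 595 at gene ends (separation of 1 kb), 1647 and 1171 with peaks of q up to 0.001, 1737 and 1292 at equal covered length, 2809 and 2378 with windows of 50 kb and 139 and 800 with a separation of 5 kb. The 2 other splits of the lines gave 337 and 156 genes, and 748 and 226 genes. Control-only bins numbered 25410 and mutant-only bins 7322, against 2089 and 6845, and 7137 and 5078, for the other splits. Of the mutant-only bins 53.2% lay within 2.5 kb of a gene end, compared with 9.77% of the control-only bins. Total cover was 127 ± 11.2 Mb (SD, n = 2) in control and 115 ± 7.47 Mb (SD, n = 2) in mutant lines, a difference of -12.2 Mb. It was larger than either SD, but the groups overlapped, with 236L (120 Mb) above 159-1 (119 Mb; exact permutation p = 0.667, where 0.333 is the smallest possible). With peaks of q up to 0.001 alone that difference was 0.677 Mb, in the opposite direction. The genes with more and with less H3K4me1 numbered 6502 and 3337 without 236R and 2214 and 2768 without 236L. Without 159-1 there were 2700 with less, and without 1014 there were 1976 with more. With 1 line left out, control-only bins numbered 50913 without 159-1, 38250 without 1014, 30768 without 236L and 63927 without 236R, and mutant-only bins numbered 10668 without 159-1, 10593 without 1014, 27586 without 236L and 78289 without 236R.

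Of 13 gene lists, 4 changed in H3K4me1 against matched random lists. Cover of the 39 HOX genes rose by 15.2 percentage points, where random lists moved by 1.62 (permutation p = 1e-05, the smallest that 100000 permutations can give; adjusted p = 6e-05). With members whose windows overlap merged into 5 loci the rise was 15.2 points (adjusted permutation p = 0.0137; 6e-05 to 0.0137 over 8 alternatives). The rise was in the Hoxa (0.593, 0.572, 35.6 and 35.6% in 159-1, 1014, 236L and 236R), Hoxc (4.36, 0.427, 19.1 and 22.5%) and Hoxd genes (4.58, 3.31, 20.8 and 28.4%) and not in the Hoxb genes (29.9, 46.3, 12.9 and 34.7%). Over the list 25 members had at least 2 kb more in both mutant lines, 1 had less (Hoxb1, 6.49, 7.89, 0 and 2.78 kb) and 13 did neither. The list of 18 antigen presentation genes rose by 11.5 points (random lists 3.39, adjusted permutation p = 0.000327), with 7 members higher, 0 lower and 11 neither. Without 236L the rise was 6.03 points (adjusted permutation p = 0.0175; 0.000126 to 0.0175 over 8 alternatives). Members that were higher included the peptide transporter Tap1 (3.59, 2.99, 9.64 and 10.3 kb) and the immunoproteasome subunit Psmb8 (2.58, 1.95, 7.28 and 9.33 kb). Both are neighbours on chromosome 17 whose windows overlap, so they largely count the same peaks and are not separate loci. Merging members with overlapping windows is among the 8 alternatives. In this list 236L stood above 236R, at 26.6 against 15.6% of the window, with 9.36 and 9.72% in the control lines. A list of 24 macrophage genes had 40.7% of its H3K4me1 windows covered in 236L and 12.0% in 236R, with 14.7 and 18.2% in the control lines. The 40 developmental transcription factors rose by 5.84 points (random lists 2.68, adjusted permutation p = 0.0490; 11 members higher, 2 lower, 27 neither) and the 16 housekeeping genes by 7.62 (random lists 1.31, adjusted permutation p = 0.0429; 7 higher, 0 lower, 9 neither). Without 1014 these adjusted p-values were 0.127 and 0.0856, and without 236R they were 0.820 and 0.379. Over 8 alternatives they ranged from 7e-05 to 0.820 and from 0.00275 to 0.379.

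Lung epithelial genes had a difference of -6.00 points (adjusted permutation p = 0.0952; 0 higher, 3 lower, 12 neither) and immune cell genes of 5.54 points (adjusted permutation p = 0.113; 0 higher, 0 lower, 15 neither), and neither list passed. Without 159-1 the lung list passed (adjusted permutation p = 0.0444), and without 236R the immune list did (adjusted permutation p = 0.00103), at 15.1 points. With windows of 50 kb the immune list also passed (6.16 points, adjusted permutation p = 0.00445). Over 8 alternatives the adjusted p ranged from 0.0444 to 0.564 for the lung list and from 0.00103 to 0.604 for the immune list. The immune cell genes had 25.0% in 236L and 5.83% in 236R, with 10.0 and 9.71% in the control lines. The remaining lists had adjusted permutation p-values of 0.565 or more: NEUROD1 neuronal (4 higher, 2 lower, 14 neither; without 236L 7.93 points with an adjusted permutation p of 0.00136), POU2F3 tuft (0, 2 and 11), Notch YAP non-neuroendocrine (3, 2 and 18), COMPASS and KDM6 genes (1, 1 and 12), PRC2 genes (0, 1 and 11), fibroblast and endothelial cells (1, 1 and 13) and engineered loci (0, 0 and 4).

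**Figure D2:**
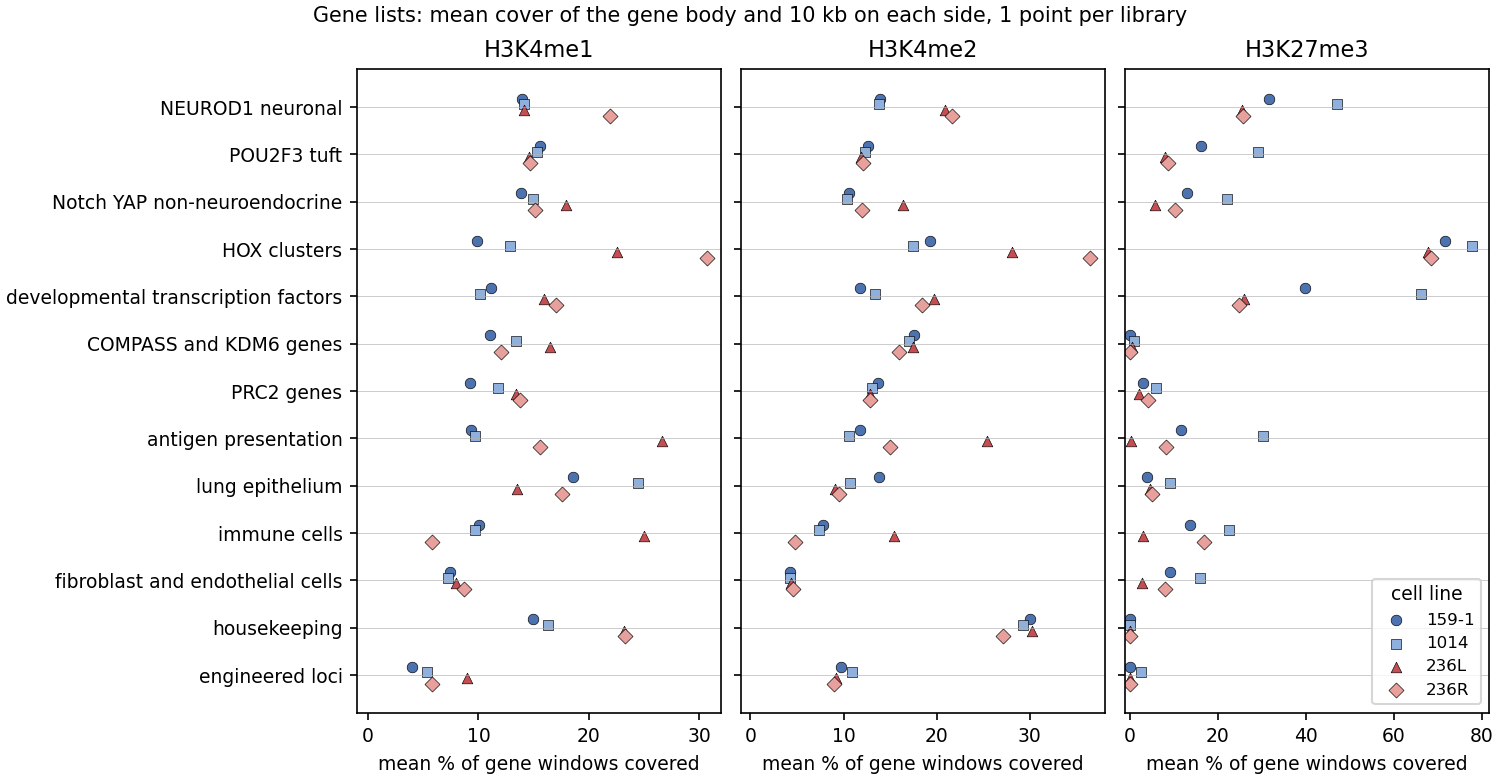
Mean share of the gene window (gene body with 10 kb on each side) covered by peaks, in percent, for each of 13 gene lists and each line, 1 panel per mark and 1 point per library. HOX genes have more H3K4me1 in 236L (22.6%) and 236R (30.7%) than in the control lines (9.90 and 12.9%).

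H3K4me2 was at least 2 kb above control in both mutant lines at 28 of 39 HOX genes and 14 of 40 developmental transcription factors. Zeb2, a repressor that drives mesenchymal programmes, had 4.92 and 8.63 kb in the control lines, 28.9 kb in 236L and 26.5 kb in 236R. Hoxa3 had 1.78 and 0.571 kb against 20.1 and 17.4 kb, Gata3 1.30 and 2.44 kb against 10.998 and 12.2 kb, and Nr2f1, a nuclear receptor of the developing nervous system, 3.69 and 3.49 kb against 12.2 and 12.1 kb. Lower values were found at Gse1, a corepressor component (130.3, 122, 64.4 and 71.99 kb), Msi2 (83.0, 81.6, 16.7 and 41.1 kb), Camta1 (88.4, 79.0, 28.7 and 39.2 kb), Nav2 (65.3, 64.5, 22.7 and 26.8 kb) and the chromatin remodelling subunit Arid1b (60.3, 59.7, 27.03 and 24.1 kb).

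In H3K4me2, 298 genes had at least 2 kb more in both mutant lines and 1395 at least 2 kb less (3042 and 5556 by any amount, and 358 and 389 at gene ends with a separation of 1 kb); the other splits gave 108 and 123, and 74 and 37. Control-only bins numbered 13073 and mutant-only bins 3373, compared with 1356 and 3248, and 1512 and 1149, for the other splits. Total cover was 86.4 ± 1.74 Mb (SD, n = 2) in control and 74.9 ± 1.74 Mb (SD, n = 2) in mutant lines, with both mutant lines below both control lines (exact permutation p = 0.333, the smallest possible). At equal covered length the genes with less H3K4me2 numbered 803 and the control-only bins 8620. The counts of genes with more and with less were 2251 and 2520 without 236R, 582 and 2113 without 236L, and 469 and 457 genes had more without 159-1 and without 1014; without 1014 the count with less was 2112. With 1 line left out, control-only bins numbered 23251 without 159-1, 21753 without 1014, 15446 without 236L and 24793 without 236R, and mutant-only bins numbered 4988 without 159-1, 5473 without 1014, 10340 without 236L and 23733 without 236R.

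Of the 13 lists, 5 changed in H3K4me2. HOX genes rose by 13.9 points (random lists 0.261), with 28 of 39 members higher in both mutant lines, 1 lower and 10 neither (1 of the 10 Hoxb genes was higher, at a mean cover of 67.7, 61.9, 30.3 and 71.9%), NEUROD1 neuronal genes by 7.43 (random lists 0.104), developmental transcription factors by 6.51 (random lists -0.0971) and antigen presentation genes by 9.03 (random lists 0.263), each with a permutation p of 1e-05, the smallest that 100000 permutations can give, and an adjusted p of 6e-05. Among the 20 NEUROD1 neuronal genes, transcription factors of neuronal differentiation, 8 were higher, 1 lower and 11 neither. Otx2 had 0 kb in both control lines and 6.74 and 5.82 kb in 236L and 236R, Lhx9 6.07, 5.91, 13.3 and 11.58 kb, and Olig2 1.04, 0.448, 4.93 and 6.93 kb, while Neurog3 had 8.99, 10.3, 2.87 and 4.98 kb. At Neurod1 itself the values were 2.82, 4.50, 3.52 and 4.06 kb. Of the developmental transcription factors 14 were higher, 1 lower and 25 neither, with Pax3 at 1.945, 2.52, 8.43 and 10.5 kb and Pax6 at 3.11, 3.32, 16.1 and 8.09 kb. With windows of 50 kb around genes the NEUROD1 list no longer passed (adjusted permutation p = 0.0640; 6e-05 to 0.0640 over 8 alternatives). The random lists were not matched on control H3K27me3. In 159-1 and 1014 it covered 71.7 and 77.8% of the HOX, 31.6 and 47.1% of the NEUROD1 and 39.8 and 66.2% of the developmental windows. The rises of these lists are thus not told apart from a rise at genes with H3K27me3 in the control lines. Of the antigen presentation genes 4 were higher and 14 neither, and 236L (25.4%) stood above 236R (15.0%). The 4 include the neighbours Tap1 and Psmb8 with overlapping windows, so they are not 4 separate loci. Their rise was 3.81 points without 236L and 14.2 without 236R (adjusted permutation p = 0.00136 and 7e-05; 6e-05 to 0.00136 over 8 alternatives). The macrophage genes had 26.2% of their H3K4me2 windows covered in 236L and 7.87% in 236R.

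Notch and YAP pathway genes of non-neuroendocrine cells rose by 3.75 points (random lists -0.201, adjusted permutation p = 0.000588; 4 higher, 1 lower, 18 neither), among them the mesenchymal regulator Twist1 (1.72, 2.13, 6.04 and 5.68 kb) and the receptor kinase Axl (6.26, 5.83, 15.4 and 8.61 kb). Without 236L the rise was 1.53 points (adjusted permutation p = 0.0303) and without 236R 5.97 points, and with windows of 50 kb the list did not pass (adjusted permutation p = 0.0911; 6e-05 to 0.0911 over 8 alternatives). Single genes with less H3K4me2 in both mutant lines included the survival gene Bcl2 (14.0, 14.2, 5.33 and 5.05 kb), the stem cell factor Sox2 (11.8, 11.04, 4.67 and 4.73 kb) and the Notch ligand Dll3 (11.01, 11.3, 6.64 and 8.96 kb). The other 8 lists did not pass: POU2F3 tuft (1 higher, 1 lower, 11 neither), COMPASS and KDM6 genes (0, 1 and 13), PRC2 genes (0, 1 and 11), lung epithelium (0, 1 and 14; adjusted permutation p = 0.162, and 0.0388 without 1014), immune cells (0, 0 and 15; 0.162, and 0.0443 without 236L and 0.00164 without 236R, in opposite directions), fibroblast and endothelial cells (1, 1 and 13), housekeeping (0, 1 and 15) and engineered loci (0, 1 and 3, with Rb1 as the lower one). Under other settings some of these passed. With gene ends alone the immune list rose by 9.98 points (adjusted permutation p = 0.000373) and the lung list fell by 3.97 (adjusted permutation p = 0.0220). With windows of 50 kb the immune list (2.19 points, adjusted permutation p = 0.00445), the PRC2 genes (0.820 points, 0.0395) and the housekeeping genes (1.27 points, 0.00794) passed. The raw changes of the latter pair had the opposite sign to their main values of -0.515 and -0.976 points. Those main values already lay above their random lists (-0.937 and -3.06 points). Over 8 alternatives the adjusted p ranged from 0.000373 to 0.152 for immune cells, 0.0220 to 0.433 for lung epithelium, 0.0395 to 0.973 for PRC2 genes and 0.00794 to 0.709 for housekeeping genes. The lower member of the COMPASS and KDM6 genes was Uty on chromosome Y. At Pou2f3, the factor that defines the tuft subtype, H3K4me2 covered 1.05 and 2.06 kb in the control lines and 4.68 and 6.497 kb in the mutant lines.

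**Figure D3:**
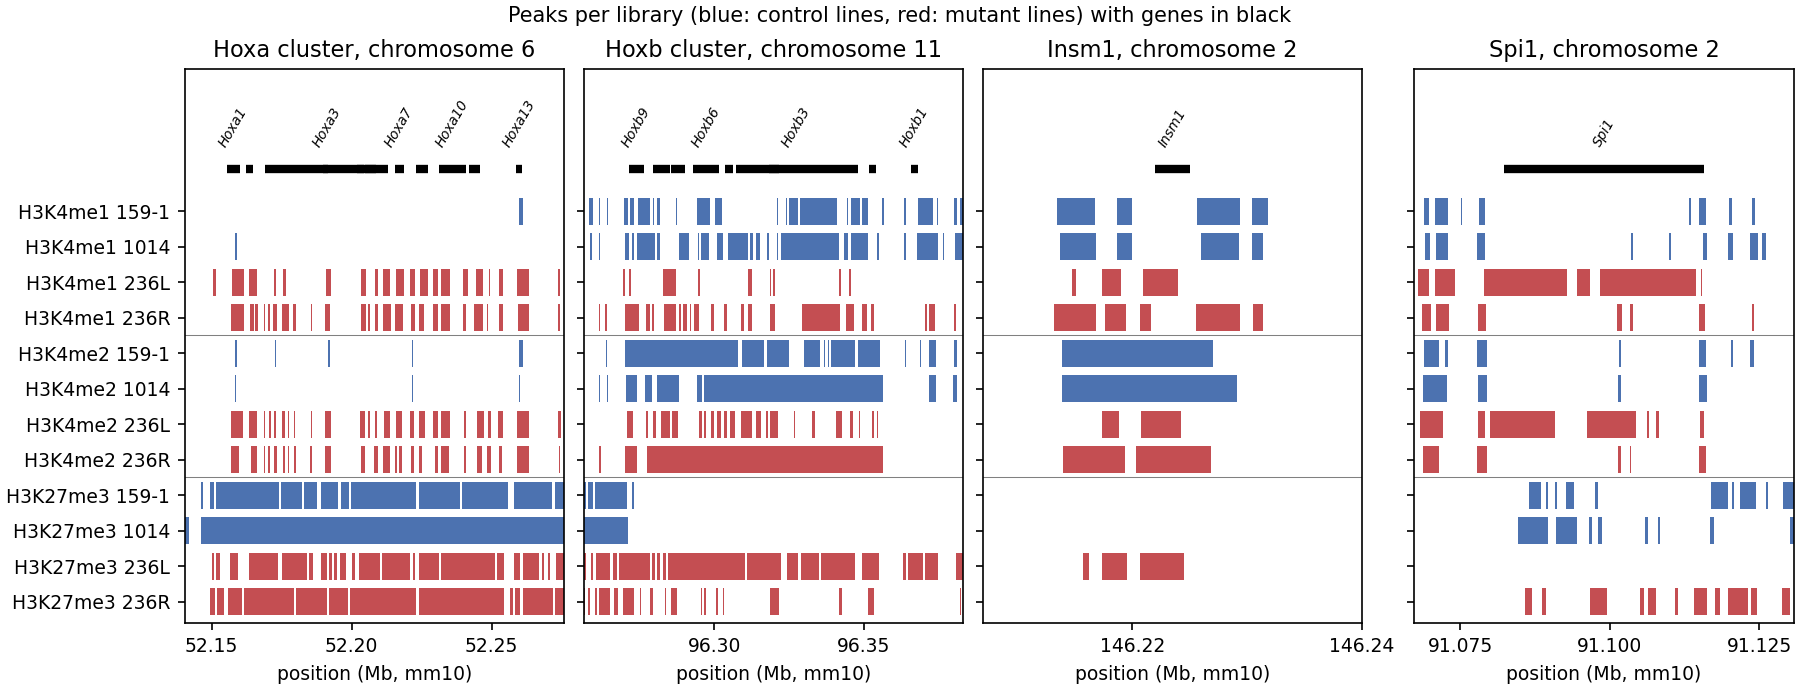
Peaks of each library along the Hoxa and Hoxb clusters, Insm1 and Spi1 (position in Mb, mm10), with control lines in blue, mutant lines in red and genes as black bars. H3K4me1 and H3K4me2 peaks lie across the Hoxa cluster in both mutant lines, and H3K27me3 lies over Insm1 in 236L (6.54 kb) and in no other line.

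H3K27me3 was below control in both mutant lines by long lengths, summed over the peaks of the gene window, at single genes. Csmd2 had 349 and 245 kb in the control lines and 11.5 and 38.3 kb in 236L and 236R. The axon guidance gene Slit3 had 218, 372, 8.81 and 65.8 kb, the glutamate receptor gene Grik3 212, 212, 17.5 and 94.3 kb, and Gli2, a transcription factor of the Hedgehog pathway, 124, 194, 3.62 and 7.13 kb. Fewer genes were higher in both mutant lines: the RNA-binding protein gene Msi1 (0, 0, 25.5 and 31.0 kb), Bcor, a subunit of a Polycomb repressive complex on chromosome X (0, 0, 13.5 and 18.7 kb), the patterning gene Hoxb3 (0, 0, 51.0 and 7.88 kb) and Sox2 (0, 0, 7.48 and 8.26 kb). Chromosome X held 0.132 and 0.230% of the H3K27me3 cover in the control lines and 1.28 and 3.85% in 236L and 236R. Pou2f3 had 63.3, 93.2, 8.22 and 38.2 kb and Neurod1 5.196, 14.0, 0.461 and 0 kb.

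In H3K27me3, 93 genes had at least 2 kb more in both mutant lines and 1407 had less (466 and 2660 by any amount); the other splits gave 489 and 3, and 211 and 55. Control-only bins numbered 19456 and mutant-only bins 488, against 96 and 6613, and 926 and 1368. Total cover was 77.8 ± 45.9 Mb (SD, n = 2) in control and 22.2 ± 11.9 Mb (SD, n = 2) in mutant lines (exact permutation p = 0.333, the smallest possible), and the spread of the control lines was nearly as large as the difference of -55.7 Mb. With all lists trimmed to equal covered length the genes with more and with less numbered 192 and 318, and the control-only and mutant-only bins 2022 and 889. Without 159-1 there were 3698 genes with less H3K27me3, without 236R 880 with more and 2203 with less, without 236L 465 with more, and without 1014 219 with more. With 1 line left out, control-only bins numbered 84208 without 159-1, 28414 without 1014, 21047 without 236L and 27078 without 236R, and mutant-only bins numbered 567 without 159-1, 1315 without 1014, 8178 without 236L and 5302 without 236R.

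Against random lists matched on control H3K27me3, 1 of the 13 lists differed. HOX genes decreased by 6.69 points where random lists moved by -28.3 (permutation p = 1e-05, the smallest that 100000 permutations can give; adjusted p = 6e-05), with 7 members higher in both mutant lines, 10 lower and 22 neither. Without 1014 the decrease was 3.61 points (adjusted permutation p = 6e-05), and with members merged into 5 loci it was 7.30 points (adjusted permutation p = 0.0128; 6e-05 to 0.0128 over 8 alternatives). The 4 clusters differed from each other: the Hoxa genes had 91.9, 99.7, 73.7 and 91.5% of their windows covered, the Hoxc genes 96.8, 100, 77.5 and 94.2%, the Hoxd genes 85.9, 99.3, 37.2 and 62.4%, and the Hoxb genes 14.0, 14.5, 79.7 and 25.1%. The 7 higher members were all in the Hoxb cluster, which also carried KDM6A in the control lines (41.6 and 38.9% of the windows). Insm1, a transcription factor of endocrine cells, had 6.54 kb of H3K27me3 in 236L and 0 kb in the 3 other lines, Foxa2 7.93 kb and 0 kb, and Nkx2-1 6.09 kb and 0 kb.

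The other 12 lists did not differ from random lists in H3K27me3, where the matched lists of all but the COMPASS and KDM6 genes and the housekeeping genes themselves lost cover. Their members numbered 1 higher, 4 lower and 15 neither for NEUROD1 neuronal genes (adjusted permutation p = 0.0677; p = 0.0444 without 159-1, 0.0264 without 1014 and 0.00186 without 236R), 1, 4 and 8 for POU2F3 tuft, 0, 7 and 16 for Notch YAP non-neuroendocrine, 0, 20 and 20 for developmental transcription factors (p = 0.618; 0.0264 without 1014 and 6e-04 without 236R), 0, 5 and 13 for antigen presentation, 0, 2 and 13 for immune cells (p = 0.252; 0.0175 without 236L), 0, 2 and 13 for fibroblast and endothelial cells, and 0, 1 and 14 for lung epithelium. COMPASS and KDM6 genes, PRC2 genes, housekeeping genes and engineered loci had 0 members higher or lower. At equal covered length the immune list moved from -8.16 points (random lists -11.4) to 5.21 (random lists 1.26, adjusted permutation p = 0.00855) and the lung list from -1.79 (random lists -3.86) to 4.24 (adjusted permutation p = 0.0104). Both raw changes thus turned from a decrease to a rise, and both lists passed. Relative to random lists the direction of the immune list did not change, since it lay above them in both settings. With gene ends alone the NEUROD1 neuronal genes (-12.9 points, adjusted permutation p = 0.00231) and the developmental transcription factors (-26.0 points, 0.0146) passed. Over 8 alternatives the adjusted p ranged from 0.00855 to 0.789 for immune cells, 0.0104 to 0.493 for lung epithelium, 0.00186 to 0.774 for NEUROD1 neuronal genes and 6e-04 to 0.905 for developmental transcription factors. At Pax5 the values were 105.8, 153, 23.5 and 4.56 kb, at Gata3 34.2, 41.5, 12.1 and 19.4 kb, at Neurog2 14.0, 22.9, 6.93 and 1.94 kb, and at the coactivator Nlrc5 10.4, 61.4, 0 and 0 kb.

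KDM6A occupied gene ends and active chromatin in the control lines. Its longest cover, summed over the peaks of a gene window, was at Gse1 (97.0 and 101.6 kb in 159-1 and 1014) and Aopep (44.8 and 54.2 kb). Next were the ephrin receptor Ephb2 (39.5 and 40.9 kb), Camta1 (43.4 and 34.7 kb) and Msi2 (46.8 and 32.1 kb). Single KDM6A peaks were at most 13.5 kb long in 159-1 and 14.6 kb in 1014. The transcription factors Nkx2-1 (13.5 and 14.4 kb), Foxa2 (12.6 and 11.4 kb) and Insm1 (9.02 and 7.49 kb) were covered in both lines, while Neurod1 had 0.472 and 0.863 kb and Pou2f3 0 and 0.735 kb. Of 16297 bins bound in both lines, 55.5% lay within 2.5 kb of a gene end, compared with 6.69% of all bins. H3K4me2 marked 90.3% of the bound bins in both control lines (shifted bins 2.84%) and H3K4me1 37.5% (shifted bins 3.79%), each above all 1000 shifts (permutation p = 0.000999, the smallest these can give). H3K27me3 marked 1.38% (shifted bins 1.45%, permutation p = 0.597). H3K27me3 together with H3K4me1 or H3K4me2 marked 1.18% (shifted bins 0.0853%, permutation p = 0.000999), or 192 of the 225 bound bins with H3K27me3. Only 4.53% of the bound bins carried none of the 3 marks. The joint mark thus lies above shifted bins because bound bins mostly carry an H3K4 mark, and its p shows no excess of H3K27me3 there.

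From control to mutant lines, bins bound by KDM6A lost H3K4 methylation less often than unbound bins of similar rank. H3K4me1 marked in both control lines was absent from both mutant lines in 346 of 6113 bound bins (5.66%) and 25064 of 80221 unbound bins (31.2%), a stratified odds ratio of 0.176 (95% interval 0.154 to 0.2002). For H3K4me2 the shares were 9.48 and 22.2% and the odds ratio 0.640 (0.582 to 0.703). Under other settings the ratio for H3K4me2 was 0.337 at gene ends, 0.733 at distal bins and 0.368 unstratified, and for H3K4me1 it was 0.296 with bins bound in either line. Without 236R the odds ratio for H3K4me1 was 0.702. Ratios in the 2 other splits were 0.240 to 0.608 for H3K4me1 and 0.0344 to 0.0836 for H3K4me2, and from mutant to control lines 1.04 and 0.0273. These are no reference for genotype, because bound bins were chosen by binding in both control lines and each of these losses needs a control line without the mark. The lower loss at bound bins is thus not tied to the mutation by these ratios. Gain of H3K27me3 was counted among bins with H3K4me1 or H3K4me2 in both control lines and H3K27me3 in neither. Of these, 49 of 15070 bound bins and 143 of 103651 unbound bins carried H3K27me3 in both mutant lines, an odds ratio of 1.56 whose interval includes 1 (0.975 to 2.4997). Without 236L that ratio was 0.930, without 1014 0.959 and without 236R 2.99. Under some other definitions given below, among them the unstratified ratio of 2.36, the interval lay above 1. At equal covered length the ratio fell below 1.

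Bins that had H3K4me1 only in the control lines and H3K27me3 only in the mutant lines numbered 24, against 5.36 in shifted bins (permutation p = 0.000999, the smallest that 1000 shifts can give, one-sided). With lists of equal covered length there were 12 (permutation p = 0.172) and with the stricter threshold 0. Bins that gained both H3K4me1 and H3K27me3 numbered 29, against 1.74 in shifted bins (permutation p = 0.000999), and 168 bins gained H3K4me1 where H3K27me3 was confined to the control lines, against 59.6 (permutation p = 0.000999). For H3K4me2, 214 bins gained it in both mutant lines where H3K27me3 was confined to the control lines, against 26.8 in shifted bins (permutation p = 0.000999). Another split of the lines gave an enrichment of 8.70 from 9 bins, against 7.87 for these 214 bins, though it rests on the labels of the control H3K4me2 lists. Bins that lost H3K4me2 and gained H3K27me3 numbered 9, against 2.92 in shifted bins (permutation p = 0.00799). Bins that gained both H3K4me2 and H3K27me3 numbered 14, against 0.725 in shifted bins (permutation p = 0.000999). The shifts did not keep nearness to gene ends, where 41.6% of the H3K27me3 mutant-only bins lay, against 6.69% of all bins. Joint gains with H3K27me3 were enriched 16.6 times for H3K4me1 and 19.3 times for H3K4me2, and losses with its gain 4.48 and 3.08 times. These p-values thus cannot tell an exchange of marks apart from a shared location near genes.

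The 2 mutant lines differed from each other in H3K4me1 more than the control lines did. The Jaccard index of covered bases, which is 1 for identical lists, was 0.566 between 159-1 and 1014, 0.444 and 0.401 between 236R and these, and 0.144, 0.150 and 0.170 between 236L and 159-1, 1014 and 236R. H3K4me2 gave 0.688 between the control lines, 0.563 and 0.582 for 236R, and 0.414, 0.406 and 0.484 for 236L. H3K27me3 gave 0.282 between the control lines and 0.0680 to 0.212 for the other pairs. KDM6A gave 0.435. 236L had H3K4me1 over myeloid genes, named here after their values were seen: the transcription factor Spi1 had 34.2 kb in 236L and 4.39, 5.63 and 4.77 kb in 159-1, 1014 and 236R, the receptor Csf1r 27.7 kb and 2.22, 2.12 and 0.239 kb, the leukocyte antigen Ptprc 22.1 kb and 0, 0 and 0.469 kb, and the macrophage antigen Adgre1 17.2 kb and 0 kb in each other line.

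**Figure D4:**
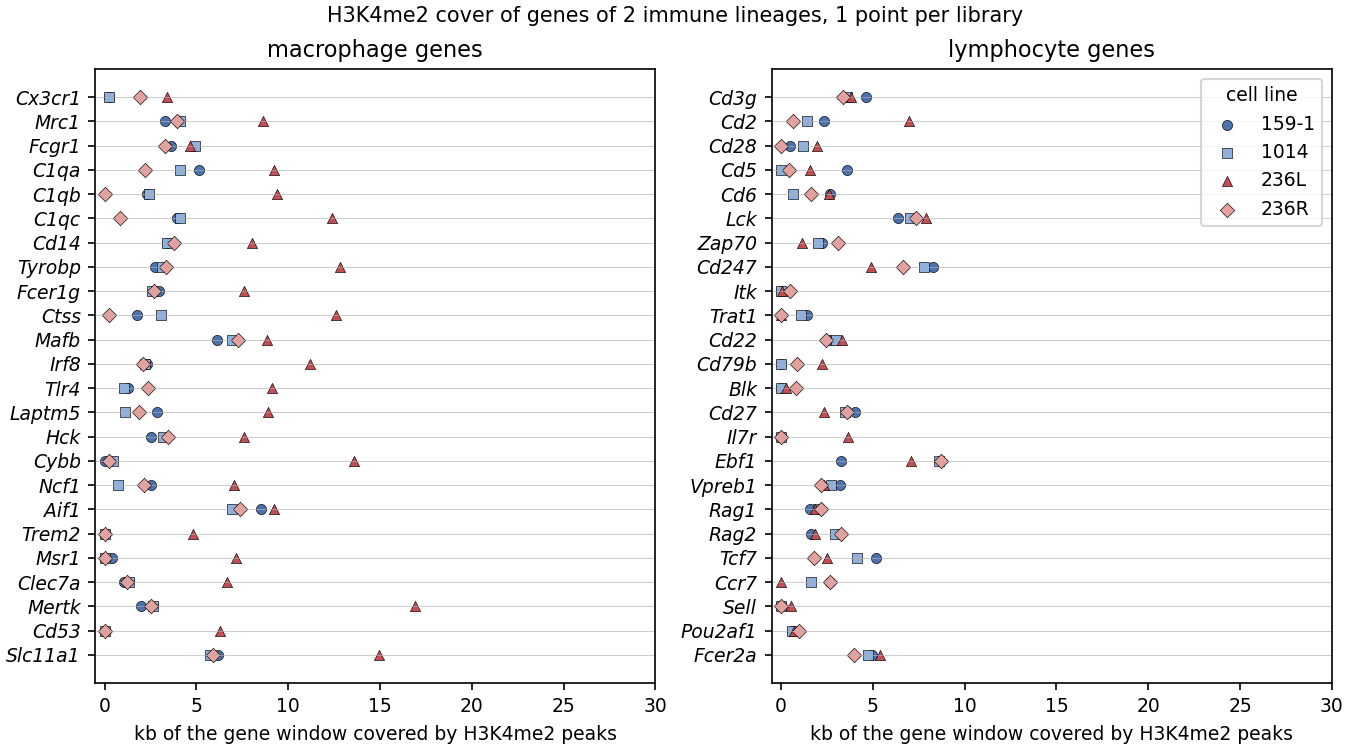
Length covered by H3K4me2 peaks in the window of each macrophage gene and each lymphocyte gene (kb, 1 point per gene) in each of the 4 lines. In 236L the macrophage genes have a mean of 26.2% of the window covered, compared with 9.17, 8.82 and 7.87% in 159-1, 1014 and 236R.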

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

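The tests on the myeloid lineage of 236L and on the length of its peak lists were set down before their results were seen, and the tests on kept bins, on the immune list in 236R, on exchanged labels and on H3K27me3 length were chosen only after the result was seen.

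The 2 mutant lines moved in opposite directions from the control lines at the secretory granule gene Chga and at immune genes, and the differences between them were not tested. H3K4me1 at Chga covered 2.74 kb in 236L and 15.1 kb in 236R (difference -12.4 kb), against 11.3 and 11.9 kb in the control lines. The immune cell list had 19.1 percentage points more H3K4me1 and 10.6 points more H3K4me2 in 236L than in 236R. Peaks on unplaced contigs, which no comparison uses, covered a mean of 37.8 kb for H3K4me1 in the mutant lines (41.9 and 33.7 kb, control lines 9.99 and 22.6 kb) and 51.7 kb for H3K4me2 (62.9 and 40.5 kb, control lines 22.2 and 17.1 kb).

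236L carried active marks over macrophage genes. A list of 24 such genes had more H3K4me2 in 236L than 100% of random lists (26.2% of the window), and at most 12.0% of random lists lay below it in the other lines; 24 lymphocyte genes lay above 2.46% in 236L. All 24 macrophage genes had at least 2 kb in 236L and 15, 15 and 14 in 159-1, 1014 and 236R, with the adaptor Tyrobp at 2.75, 3.13, 12.8 and 3.32 kb and the protease Ctss at 1.74, 3.07, 12.6 and 0.264 kb in 159-1, 1014, 236L and 236R. For H3K4me1 the list also lay above 97.2% of random lists in 1014. A small share of immune cells among tumour cells would leave tumour sites in place, but 236L marked 30.7% of the H3K4me1 bins of the 3 other lines, where 236R marked 76.1%. For H3K4me2 these shares were 77.5 and 94.4%, so for this mark a small share of immune cells cannot be told apart from a larger one. List length is not the account for H3K4me1, since the immune list in 236L lay above 99.1% of random lists at equal covered length, with 50.3% as the highest other line. For H3K4me2 in 236L it lay above 89.2% at equal covered length and 91.0% with the main lists. With the main H3K4me1 lists 236R lay above 3.91% where 236L lay above 99.3%. The immune list was flagged for the difference between these mutant lines, so the low value in 236R is no independent test of a shared effect. A culture made up largely of myeloid cells may be the source of the 236L peaks for H3K4me1, and tumour cells with a myeloid programme, an effect of the mutation in this line alone or exchange with an outside sample stay open as untested. Values of the mutant group that rest on 236L cannot be read as an effect of genotype while this is open.

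The 2 control H3K4me2 lists differed from each other in the direction opposite to the other control lists. Of 2265 bins outside chromosome 19 that differ between the control lines in both H3K4me2 and KDM6A, 28.8% had the same direction. Over all chromosomes at equal covered length the share was 23.9% of 2119 bins, which argues against list length. H3K4me1 and KDM6A had the same direction in 56.3% of bins and H3K4me1 and H3K4me2 in 24.7%. Exchanged labels are a candidate explanation that also fits the names of the 2 lists, and H3K4me2 is the mark out of step. Chromosome 19 held 1.14, 0.541 and 1.29% of the H3K4me1, H3K27me3 and KDM6A cover in 159-1 against 2.80, 4.03 and 3.05% in 1014, but 3.15 and 2.17% of the H3K4me2 cover. An exchange of the 3 other assays together in place of H3K4me2 was not excluded, and no biological explanation was tested.

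H3K27me3 peaks covered less of the genome in both mutant lines. At equal covered length the ratio of control-only to mutant-only bins was 2.27, with 1.89 as the highest of the other splits, and weaker enrichment of the mutant libraries cannot be told apart from fewer marked sites, since no read counts were used. 236R alone covered 30.5 Mb, under the lower control line (45.4 Mb) by less than the 64.9 Mb between the control lines. The 3 splits of the lines allow no p below 0.333, so an effect of genotype also stays open.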

How the results depend on the processing

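All alternatives for single genes, and for lists leaving out lines and merging neighbours, were chosen only after the result was seen; the other alternatives were set down before the data were examined. No paired analysis was possible because the replicates are different cell lines and their numbers only name them.

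Among the results that answer a comparison, 92 values under an alternative kept their direction and range or call, 76 moved, 4 became stronger, 1 weaker and 2 reversed. For lists and single genes 1720 kept theirs, 739 moved, 22 became stronger, 10 weaker and 2 reversed. The cause was not tested, except that stricter settings leave fewer peaks and wider ones hold more.

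With peaks of q up to 0.001 the difference in covered length was 0.677 Mb for H3K4me1, a reversal, and -21.5 Mb for H3K27me3. For H3K27me3 this left 4002 control-only and 33 mutant-only bins, 10 genes with more and 585 with less, and the overlap of H3K4me1 loss with H3K27me3 gain was 0 bins (p = 1, permutation). Another split of the lines gave 11 and 1350 H3K27me3 bins at this threshold. With bins marked at any overlap, control-only and mutant-only bins numbered 41382 and 12190 for H3K4me1, 25459 and 5432 for H3K4me2 and 33217 and 1045 for H3K27me3. With full cover required they numbered 14727 and 3308, 5590 and 1910, and 11315 and 167. Merged regions gave 14585 and 4120 for H3K4me1, 1915 mutant-only for H3K4me2 and 8161 control-only for H3K27me3. At equal covered length there were 8620 control-only bins for H3K4me2 and 2022 and 889 bins for H3K27me3, 803 genes with less H3K4me2, 192 genes with more and 318 with less H3K27me3, an odds ratio of gain of 0.850 and an overlap of 12 bins (permutation p = 0.172).

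Windows of 50 kb gave 2809 genes with more and 2378 with less H3K4me1, 688 with more and 2715 with less H3K4me2, and 239 with more and 2702 with less H3K27me3. In these windows the developmental list moved by 0.856 points in H3K4me1, below random lists, and the separation at the PRC2 gene Ezh1 was 0.95 kb in H3K4me1, also reversed. A separation of 5 kb gave 139 and 800 genes for H3K4me1, 48 and 415 for H3K4me2 and 25 and 771 for H3K27me3. Gene ends with the separation lowered to 1 kb gave 1611 genes with more and 595 with less H3K4me1, and 358 and 389 for H3K4me2. Windows of 50 kb and gene ends at 1 kb of separation thus gave more genes with more than with less H3K4me1, unlike the main 1160 and 1630, as did q up to 0.001 (1647 and 1171) and equal covered length (1737 and 1292). The turn at gene ends cannot be put down to the windows alone. By any amount the main windows also gave more genes with more (5489) than with less (3225). The odds ratio of gaining H3K27me3 at KDM6A-bound bins was 2.36 unstratified, 1.65 for bins bound in either line and 3.12 for distal bins, each above 1 by its interval.

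Leaving out each line in turn, control-only bins ranged from 30768 to 63927 for H3K4me1, 15446 to 24793 for H3K4me2 and 21047 to 84208 for H3K27me3, and mutant-only bins from 10593 to 78289, 4988 to 23733 and 567 to 8178. Genes with more ranged from 1721 to 6502, 457 to 2251 and 103 to 880, and genes with less from 1909 to 3337, 2010 to 2520 and 1529 to 3698. The odds ratio of gain ranged from 0.930 to 2.99. Differences in covered length kept their sign, from -20.1 to -4.24 Mb for H3K4me1, -12.7 to -10.3 Mb for H3K4me2 and -88.1 to -23.2 Mb for H3K27me3, and 13 to 15 of the 42 list tests passed. Depth is unknown, so what it limits cannot be stated.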

Other observations

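The test on long KDM6A cover was set down before its result was seen. The tests on genes with opposite marks, sex chromosomes, kept bins and mark exchange were chosen only after the result was seen.

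Some genes had less H3K4me2 and more H3K27me3 in both mutant lines. There were 21, compared with a mean of 7.08 and a highest count of 17 among 1000 draws of matched genes (permutation p = 0.000999, the smallest these can give). They included the stem cell factor Sox2 (H3K4me2 11.8, 11.04, 4.67 and 4.73 kb in 159-1, 1014, 236L and 236R; H3K27me3 0, 0, 7.48 and 8.26 kb) and the endocrine regulator Neurog3 (H3K4me2 8.99, 10.3, 2.87 and 4.98 kb; H3K27me3 0, 0, 6.99 and 9.82 kb). The reverse, more H3K4me2 and less H3K27me3, was found at 135 genes, among them Pde4b, Gata3 and Nr2f1, compared with a matched mean of 131 (permutation p = 0.306). In both counts the draws were matched on control H3K27me3 cover and window length, not on control H3K4me2, which a gene needs in order to lose it. Neighbours with overlapping windows, such as Ppp1r1b, Stard3 and Pgap3 among the 21, were counted singly. Genes are not replicates, and the other splits of the lines were not counted.

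H3K4me2 was present at 4 genes of chromosome Y in the control lines and absent in both mutant lines, with Uty at 3.27, 3.30, 0 and 0 kb, Ddx3y at 2.48, 2.62, 0 and 0 kb and Eif2s3y at 2.06, 2.57, 0 and 0 kb. Kdm5d had 0.736, 2.39, 0 and 0 kb. Total cover of chromosome Y did not follow genotype (H3K4me2 24.3, 18.3, 22.3 and 12.8 kb). The share of cover on chromosome X was higher in both mutant lines for all 3 histone marks. For H3K4me1 it was 0.474, 0.515, 1.41 and 1.18%. Total chromosome Y cover did not follow the 4 genes either, with 0 kb of H3K4me1 in 159-1 and 43.7 kb in 236L, so it is no measure of them. The 4 genes and the chromosome X share go with a difference in sex chromosomes between the groups. Such a difference cannot be told apart from genotype with these 4 lines, so it stays open. H3K27me3 bins of both control lines were also marked in 16.3% of cases by 236L and 34.9% by 236R, and those with q up to 0.001 in 45.2 and 59.5%.

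Bins that gained H3K4me2 in both mutant lines overlapped lost H3K27me3 7.87 times as often as shifted bins, which do not keep nearness to gene ends. Another split of the lines gave 8.70 from 9 bins, with a Poisson interval of 3.98 to 16.5. The other splits combine the marks by control line label, so they are no reference if the control H3K4me2 labels are exchanged. A genotype-linked exchange of the marks thus cannot be told apart from differences between lines here.

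Genes with long KDM6A cover may lose more H3K4me2 than matched genes. Among 366 pairs made from the 500 genes with the longest cover (9.52 against 4.16 kb), matched on window length and control H3K4me2, 69.9% of control H3K4me2 cover was kept compared with 74.5%, a difference of -4.68 points (SD 31.9, permutation p = 0.0054). In 236R alone it was -3.30 points (permutation p = 0.0236). At single bins the direction was the other way, since bound bins lost H3K4me2 less often than unbound bins of similar rank (odds ratio 0.640). The test of pairs sets genes against genes within these 4 lines and does not measure the spread between lines. The genes were chosen by KDM6A cover in both control lines, and other splits of the lines were not computed. Any other line could keep less at such genes, so the difference is not tied to the mutation. Neighbours with overlapping windows were counted singly.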
